A study of Mus musculus with 90 samples.

How the data were processed

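Muscle stem cells, the resident precursors that rebuild mouse skeletal muscle after injury, were profiled by bulk RNA-seq and by ATAC-seq, which measures how open chromatin is. The labels place 90 samples in 26 groups (13 RNA and 13 ATAC) by age (young or aged) and by day after injury (0, 1, 3, 5, 7 and 21), with a further young day 0 group sorted as Pax7 positive. Per the labels, cells came from digested hind limb muscles and were sorted by flow cytometry. The gates, the kind of injury and the ages are not given in the sources used here. No label says which samples came from separate animals, so p-values measure the spread between these libraries, which may be technical.

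For RNA the authors deposited RSEM expected counts per gene for 46 libraries. Per the labels' processing notes, STAR 2.5.0a, RSEM 1.3.0 and the mouse build mm10 were used; the annotation is not given in the sources used here. The authors also deposited TPM values, which were used only for their sum per library. For ATAC the authors deposited whole-number read counts in 238563 merged peaks of 200 to 3162 bases (median 268) for 40 libraries. The deposited peak lists of 44 libraries carry −log10 p and −log10 q values per peak, which are the authors' own, and 18 of the lists hold exactly 300000 peaks. bedtools is named in the processing notes, and the aligner and the peak caller of the ATAC libraries are not given in the sources used here. The 4 ATAC libraries of day 21 had peak lists and no column of counts in the table used here, so day 21 accessibility was not tested. At day 21 the ATAC libraries titled young carry the age tag aged, and the titles and descriptions were followed.

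The RNA table names 49671 Ensembl gene identifiers with symbols, and 49326 of them matched the gene name table. A line naming no gene was dropped, and 37 mitochondrial genes were left out because only some libraries had reads counted on them. Counts were rounded to whole numbers. Before libraries were averaged they were compared within their group by a chi-square over genes with 50 or more counts. The RNA library labelled young day 0 replicate 4 equalled the sum of replicates 1, 2 and 3 of its group. The median chi-square against that sum was 0.0939 times the sampling noise, its total was 143.46 M counts (M is the SI prefix mega) against 144.04 M for the 3 parts, and Pearson's r of the log counts across genes, which are not independent replicates, was 0.9991. The lowest value for any other sum of libraries of a group was 6.42 in RNA and 1.75 in ATAC, and the limit was 1. That library was left out, so 45 RNA libraries were used. The used RNA libraries held 11.82 M to 81.56 M counts (median 39.69) and the ATAC libraries 0.806 M to 22.8 M reads in merged peaks (median 5.17), of which 4 lay under 2 M. In RNA, 6 pairs of libraries differed by only 1.68 to 3.35 times the sampling noise, against 13.4 to 452.7 for the other 56 pairs of the same group. They were young day 1 replicates 1 and 4, and replicates 1 and 2 of young days 3 and 5 and aged days 0, 5 and 7. By group sizes each pair but that of young day 1 spans 2 deposited batches. Such pairs likely come from 1 sample, so p-values are likely too low. Pairs were kept separate, and every RNA comparison was also run with each pair summed (39 libraries). 

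The RNA libraries fell into 3 processing sets by traits of the deposited tables. Set A (8 libraries used) had 1.29% to 14.45% of its reads on mitochondrial genes, set B (17) had none, and set C (20) had none and TPM values that summed to less than 998000. The deposited RNA batch table lists 7 batches by day, age and sort and names no library. With the 7 batches merged into 3 classes, chosen after the data were seen so as to match the sets, set and class sizes agreed in 13 of 13 groups. Where a group spans batches its libraries could not be given one, so the main RNA model has no batch term. The ATAC batch table names each library, and its 6 batches were a term of the ATAC model.

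All RNA libraries shared 1 edgeR 4.0.16 model with a mean per group, TMM scaling and filterByExpr, which left 22432 genes. Dispersions came from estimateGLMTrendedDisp, and contrasts were tested with the quasi-likelihood F-test (robust glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment within each contrast at 0.05. The ATAC model was built the same way on 237525 peaks. Every adjusted p of a gene or peak in the text comes from these edgeR tests unless another tool is named. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM with TMM scaling, as mean ± SD over libraries. Where 1 group had no count, the fold is given as "at least", from a floor of 3 counts over that group; where it had 1 to 3 counts no fold is given. Comparisons were each day against day 0 within an age, aged against young at each day, Pax7-sorted against other sorted young cells at day 0, and the interaction of age and time.

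Gene lists (23) were fixed before the data were examined: cell cycle, chromatin modifiers, endothelial markers, erythroid markers, extracellular matrix, fibro-adipogenic progenitor markers, glial markers, glycolysis, immediate early and stress response, interferon response, lymphocyte markers, macrophage and other myeloid markers, mature myofibre markers, mural cell markers, myogenic differentiation, NF-κB and chemokines, Notch pathway, oxidative phosphorylation, quiescence and satellite cell identity, ribosome biogenesis, senescence and p53 targets, sex-linked genes, and TGF-β and BMP pathway. Each was tested in each RNA comparison with camera (limma 3.58.1) at its preset correlation of 0.01 on log CPM with a prior count of 2, adjusted over all 391 tests, and again with the correlation estimated from the data. The preset test called 159 of the 391, and with an estimated correlation it called 0 (45 at an unadjusted p under 0.05), with a lowest adjusted p of 0.201.

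Named genes followed a rule set before the data were examined: the 4 largest rises and falls (2 in the smaller comparisons) among called genes of average log2 CPM of 2 or more whose groups did not overlap, the members of a described list with the smallest p, and Pax7, Myod1, Myog and Mki67 throughout. Peaks followed the same rule with 2 each way. Peaks were placed against gene spans of GRCm38, the assembly of mm10, and coordinates count from 1. Genes that share reads with near-identical copies are uncertain, and since strandedness of the counting is not given in the sources used here, antisense partners cannot be separated.

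The groups share replicate numbers. Same-numbered libraries were checked for a correlation of their deviations from the group means, with a limit of 0.1: 34 of 85 pairs in 27 comparisons passed it (range −0.466 to 0.644). Every pair passed it in 4 comparisons. They were RNA aged day 3 and day 7 against day 0, RNA aged against young day 7 and ATAC aged against young day 3. There numbers largely follow set or batch, so pairing is not shown.

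The comparisons, lists, tests and main alternatives (DESeq2 1.42.0, its size factors, no low-count filter, library totals, no batch term, a replicate block, each replicate left out, a stricter −log10 q) were fixed before the data were examined. The sum library, the near-identical pairs, the processing sets, the ATAC read sets and their limits, and the alternatives built on them were chosen after the data were seen, as were those without libraries holding Y-linked reads (Ddx3y above 1 CPM) or fewer than 2 M ATAC reads. Refits without a replicate, and other splits of the samples (at most 100, for ATAC on 10000 peaks), reused the main dispersion trend; where 1 library was left in a group it was assumed to vary like the other groups.

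The tests were checked on simulated counts with 200 changed genes or peaks, 50 for each fold size. Recovery of 70% of 8-fold changes was asked and was reached in 4 of 7 edgeR settings. In RNA, on 22432 genes, 76% of 8-fold changes were recovered for young day 3 against day 0. Recovery was 68%, 68% and 58% for aged against young days 0, 3 and 7, and at most 4% for 2-fold changes. In ATAC, on 20000 peaks, recovery of 8-fold changes was 84% for young day 3 against day 0. For aged against young days 0 and 3 it was 84% and 100%. The highest share of false calls was 9.1% with edgeR and 32.7% with DESeq2. The data hold near-identical pairs and processing sets, so rates there may be worse. Work was done in R 4.3.3 with GenomicRanges 1.54.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

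Left out were the deposited FPKM values, since the expected counts carry the depth, and a planned analysis of promoters, since no transcription starts of mm10 were at hand.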

Results

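The series follows muscle stem cells of young and aged mice from the uninjured state (day 0) through days 1, 3, 5, 7 and 21 after muscle injury, by RNA-seq and by ATAC-seq. For RNA, the young groups held 5 libraries at day 0 (6 deposited), 4 at day 1, 5 at day 3, 3 at day 5, 4 at day 7 and 3 at day 21. The aged groups held 4, 2, 4, 2, 4 and 2 at the same days, and 3 further young day 0 libraries came from cells sorted as Pax7 positive. For ATAC, counts were at hand for 4 young and 7 aged libraries at day 0, 3 Pax7-sorted libraries, 3 and 2 at day 1, 4 and 4 at day 3, 2 and 2 at day 5, and 5 and 4 at day 7. RNA young day 0 replicate 4 matched the sum of 3 others and was left out. Values are CPM as mean ± SD over libraries, and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 22432 genes. Camera adjusted p-values use a preset inter-gene correlation, and with an estimated one none of the 391 list tests passed (lowest adjusted p = 0.201).

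Pax7, the transcription factor that marks satellite cells, averaged 49.7 ± 38.7 CPM in young (n = 5) and 90.5 ± 46 CPM in aged cells (n = 4) at day 0. Myog, which encodes the differentiation factor myogenin, stood at 138 ± 224 CPM in young and 59.1 ± 34.9 CPM in aged cells at day 0. At day 3 it was at 2040 ± 1100 CPM in young (n = 5) and 974 ± 268 CPM in aged cells (n = 4). Mki67, a marker of dividing cells, went from 4.96 ± 5.47 CPM at day 0 to 135 ± 52.7 CPM at day 3 in aged cells, and was at 29.8 ± 29 CPM and 119 ± 75 CPM in young cells. Myod1, the myogenic commitment factor, passed the test in no comparison except those of the aged day 5 libraries.

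**Figure D1:**
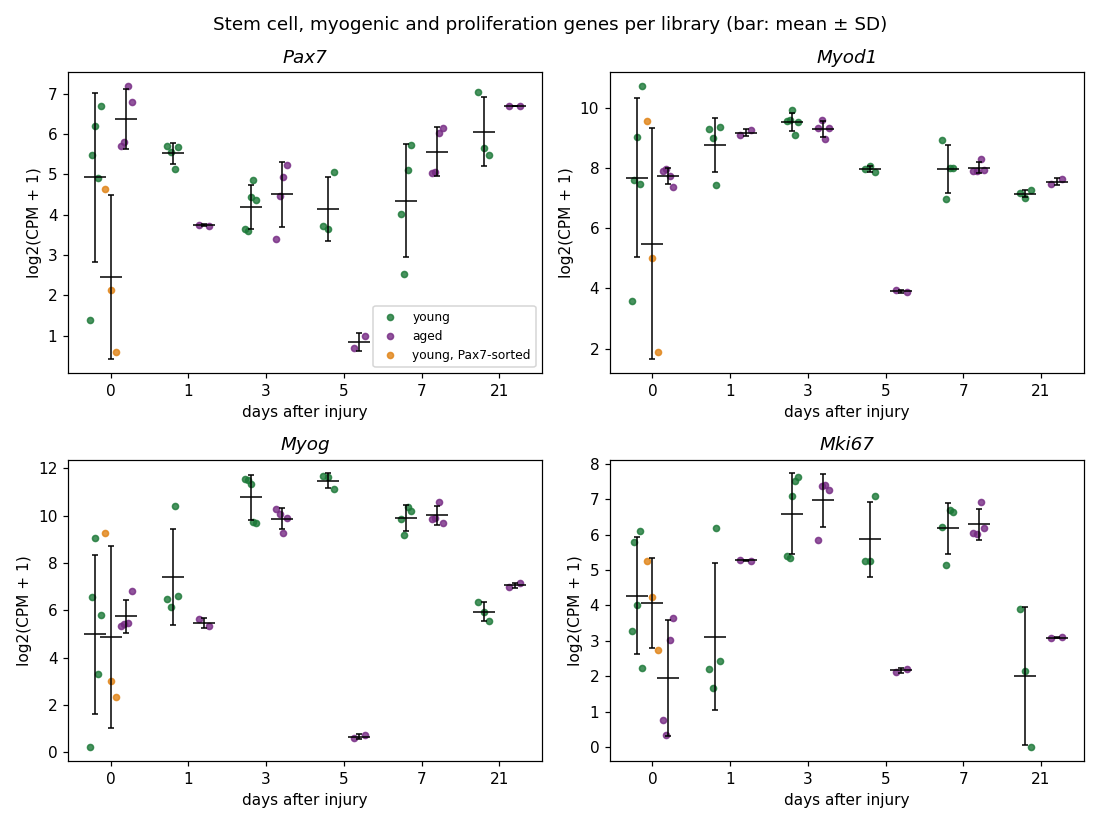
Level of Pax7, Myod1, Myog and Mki67 as log2(CPM + 1) against days after injury, with a point per RNA library, green for young, purple for aged and orange for young Pax7-sorted, and bars for the mean ± SD. Myog rises to day 3 in both ages (2040 CPM young, 974 CPM aged) and lies near 0 in both aged day 5 libraries, while a young day 1 library sits at 1370 CPM against 68.8 to 95.4 CPM in the others.

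After injury, young day 1 (n = 4) was set against young day 0 (n = 5). Nes, which encodes the intermediate filament nestin of precursor cells, rose to 52.9 ± 28.8 CPM from 7.95 ± 5.21 CPM (log2 fold change 2.73 ± 0.47 SE, adjusted p = 0.0128). Pax7 (45.3 ± 7.8 CPM) and Myod1 (491 ± 222 CPM) did not pass the test (adjusted p = 0.982 and 0.993).

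Among the lists, 9 of 22 myogenic differentiation genes rose when adjusted over the list alone and 0 over all genes. Camera placed the list higher (camera adjusted p = 1.1e-08), with a mean log2(CPM + 1) of 7.744 in replicate 3 and 5.722 in the next library. Of 10 glial markers 1 rose over all genes and 8 over the list alone (camera adjusted p = 1.26e-07). Of the 5 sex-linked genes 4 fell when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0222). The Y-linked Ddx3y had 178 CPM in young day 0 replicate 1 and 0 in the other libraries of both groups. Camera also placed mature myofibre (0.00428) and erythroid markers (0.0191) higher, the latter against a median log2 fold change of −0.055. In all, 20 genes passed (14 higher, 6 lower), against 2824 at an unadjusted p under 0.05 and 478 by DESeq2 (203 higher, 275 lower). The count was 2 without young day 0 replicate 5, 296 without young day 0 replicate 3, 248 (96 higher, 152 lower) without young day 1 replicate 3 and 0 with near-identical pairs summed.

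Young day 3 (n = 5) against day 0 (n = 5) asked what the cells express when they expand, and it moved more genes than any other RNA comparison. Myh3, the embryonic myosin heavy chain, reached 514 ± 194 CPM (log2 fold change 9.23 ± 1.55, adjusted p = 3.35e-05). Myog rose 14.8-fold (adjusted p = 0.00723). Cd34, a surface marker of satellite cells, fell to 51.9 ± 17.5 CPM from 601 ± 281 CPM (11.6-fold, adjusted p = 1.65e-07).

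Cell cycle genes rose as a group, 21 of 24 over all genes (22 over the list alone), Ccne1 6.15-fold (camera adjusted p = 3.48e-16). Myogenic differentiation genes rose in 14 of 22 cases, Tnnt2 of the troponin complex 45.9-fold (camera adjusted p = 7.64e-09). In oxidative phosphorylation 14 of 23 genes rose (camera adjusted p = 9.76e-06). In glycolysis 9 of 16 rose and 1 fell, with Eno1 5.46-fold higher (camera adjusted p = 0.000203).

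Immediate early and stress response genes fell in 19 of 22 cases, Dusp1 8.46-fold (camera adjusted p = 8.02e-11). NF-κB targets and chemokines fell in 13 of 16 cases and rose in 1, with Icam1 13-fold lower (camera adjusted p = 3.2e-05). Interferon response genes fell in 15 of 23 cases, including H2-K1, a class I antigen presentation gene, 7.41-fold (camera adjusted p = 1.85e-05). Of 25 quiescence genes 10 fell and 2 rose (camera adjusted p = 0.0928). Of 20 TGF-β and BMP genes 9 fell (camera adjusted p = 0.00164). Without a camera call, 4 of 25 extracellular matrix genes fell (adjusted p = 0.955), of 15 Notch genes 2 rose and 4 fell (0.678), of 18 senescence and p53 targets 4 rose and 3 fell (0.724), and of 22 chromatin modifiers 6 rose and 5 fell (0.318).

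Markers of other cell types mostly fell at young day 3. All 12 fibro-adipogenic progenitor markers fell, such as the stromal surface gene Ly6a 24.8-fold (camera adjusted p = 0.000176). All 12 endothelial markers fell, Flt1 32.7-fold (camera adjusted p = 3.43e-06). Of 10 glial markers 8 fell (camera adjusted p = 0.000325). All 7 erythroid markers fell (camera adjusted p = 0.00341). Mature myofibre markers rose in 4 of 14 cases and fell in 2 (camera adjusted p = 0.0102). Myeloid markers fell in 4 of 16 cases (adjusted p = 0.654), lymphocyte markers rose in 1 and fell in 2 of 12 (adjusted p = 0.225), mural cell markers fell in 5 of 10 (adjusted p = 0.0899) and sex-linked genes fell in 4 of 5 (adjusted p = 0.171), without a camera call. Young day 0 replicate 1 had the highest mean log2(CPM + 1) for myeloid (7.251, others 1.009 to 2.146), sex-linked (4.584, others 1.142 to 1.623), erythroid (6.93, others 0.992 to 4.912) and endothelial genes (8.241, others 2.486 to 4.877). For myeloid markers 3 of the 5 day 3 libraries (3.718 to 3.754) lay above those 4 others. Over all genes 7098 passed (2865 higher, 4233 lower). The count was 4799 with near-identical pairs summed and 1831 within processing set C alone.

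**Figure D2:**
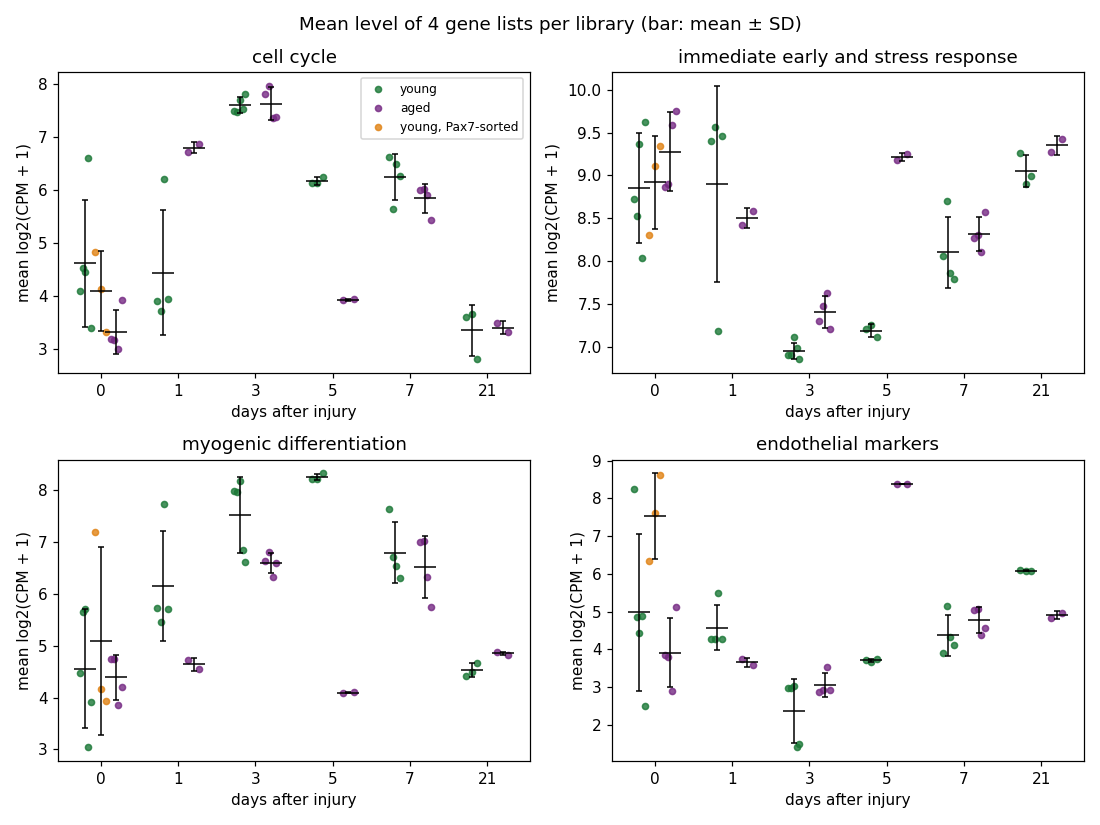
Mean log2(CPM + 1) of 4 gene lists (cell cycle, immediate early and stress response, myogenic differentiation, endothelial markers) against days after injury, with a point per RNA library, colours by group and bars for the mean ± SD. The young day 1 library at 7.744 in myogenic differentiation and 6.203 in cell cycle is replicate 3, above the next at 5.722 and 3.95.

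At young day 5 (n = 3 against 5) Myh3 was at 425 ± 120 CPM (log2 fold change 8.95 ± 1.57, adjusted p = 0.000771). Myog rose 21.1-fold to 2910 ± 583 CPM (adjusted p = 0.0237). Myogenic differentiation genes rose in 12 of 22 cases, Tnnt2 105-fold (camera adjusted p = 1.86e-17), and mature myofibre markers in 3 of 14 (4.09e-05). Endothelial markers fell in 5 of 12 cases (0.00428), fibro-adipogenic progenitor markers in 2 of 12 (0.0337) and erythroid markers in 2 of 7 (0.0402). Camera placed myeloid markers higher (0.00174), with no gene past the test and a median log2 fold change of −0.087. In all, 1223 genes passed (551 higher, 672 lower). That was 280 without young day 5 replicate 2, 1814 without young day 0 replicate 3 and 119 with near-identical pairs summed.

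At young day 7 (n = 4 against 5) Myh8, the perinatal myosin heavy chain, rose to 38.1 ± 25.9 CPM from 0.346 ± 0.685 CPM (log2 fold change 6.72 ± 1.40, adjusted p = 0.00762). Myog was at 1000 ± 329 CPM, 7.26-fold above day 0, and did not pass (adjusted p = 0.121). Cd14, a monocyte receptor, fell to 4.61 ± 2.4 CPM from 207 ± 404 CPM (adjusted p = 0.031), with 928 CPM in young day 0 replicate 1, and without that replicate the call was lost (adjusted p = 0.235).

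By list at young day 7, 8 of 22 myogenic differentiation genes rose, among them Ttn 17.6-fold (camera adjusted p = 2.59e-12). Of 25 extracellular matrix genes 3 rose and 1 fell, with the laminin gene Lamb1 3.46-fold higher (camera adjusted p = 0.000141). The lower one, Spp1, had 2470 CPM in young day 0 replicate 1. Myeloid markers fell in 3 of 16 cases, S100a8 at least 451-fold, with 40 CPM in that same replicate (camera adjusted p = 0.359). Mature myofibre markers rose in 1 of 14 (0.00696), and erythroid markers fell in 7 of 7 over the list alone and 0 over all genes (0.0387). In all, 886 genes passed (303 higher, 583 lower), against 250 without young day 7 replicate 3, 1280 without young day 0 replicate 3 and 289 with near-identical pairs summed.

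By day 21 (n = 3 against 5) none of the core genes passed the test in young cells, with Pax7 at 74.2 ± 48.3 CPM, Myog at 62.3 ± 17.4 CPM and Mki67 at 5.77 ± 7.24 CPM (adjusted p = 0.769, 0.689 and 0.311). Ncoa7, a nuclear receptor coactivator, rose 3.2-fold to 164 ± 26.3 CPM (log2 fold change 1.68 ± 0.35, adjusted p = 0.0314), and Ptx3, a secreted pattern recognition protein, fell 17-fold to 1.97 ± 1.24 CPM (adjusted p = 0.046). Cell cycle genes fell in 18 of 24 cases over the list alone and in 0 over all genes, with Top2a at 5.31 ± 7 CPM against 55.7 ± 74.1 CPM, of which 186 CPM lay in young day 0 replicate 5 (camera adjusted p = 2.49e-09). Endothelial markers were placed higher (0.00197) with a median log2 fold change of −0.022. In all, 68 genes passed (12 higher, 56 lower, or 21 and 50 with DESeq2's size factors). All day 21 libraries lie in processing set C, within which 951 passed (524 higher, 427 lower). With the processing set as a term 2409 did (1159 higher, 1250 lower). The day 21 libraries also form a deposited batch that holds no other group, so none of these counts separates day 21 from batch. Without young day 21 replicate 2 the count was 0, without replicate 3 it was 3, without replicate 1 it was 1306, and with near-identical pairs summed it was 0.

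In aged cells, day 1 (n = 2 against 4) brought a rise of cell cycle genes. Rrm2, which supplies deoxynucleotides, rose 37-fold to 579 ± 35.5 CPM (log2 fold change 5.21 ± 0.68, adjusted p = 1.71e-05). Ccl19, a chemokine, fell 14.2-fold (adjusted p = 0.0386). Cell cycle genes rose in 20 of 24 cases (camera adjusted p = 1.78e-32). Ribosome biogenesis rose in 5 of 18, Bop1 3.63-fold (camera adjusted p = 8.25e-07). Pax7 was at 12.4 ± 0.197 CPM and did not pass (adjusted p = 0.149). Camera also placed myeloid markers higher, 3 of 16 over the list alone and 0 over all genes (camera adjusted p = 0.000242), and 3 lists lower with 1 gene each over all genes: quiescence (camera adjusted p = 0.000488), immediate early and stress response (0.000502) and interferon response (0.00511). In all, 725 genes passed (591 higher, 134 lower, or 396 and 178 with DESeq2's size factors and 816 and 1112 by DESeq2). The count was 243 without aged day 1 replicate 1, 838 without aged day 0 replicate 3 and 258 with near-identical pairs summed.

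At aged day 3 (n = 4 against 4) Mki67 rose 27.1-fold to 135 ± 52.7 CPM (log2 fold change 4.76 ± 1.17, adjusted p = 0.00345), Myog 16.4-fold to 974 ± 268 CPM (adjusted p = 0.0186). Cell cycle genes rose in 22 of 24 cases, Rrm2 57.7-fold (camera adjusted p = 5.08e-28). Myogenic differentiation genes rose in 11 of 22 and fell in 1, with Ttn 76.6-fold higher (camera adjusted p = 3.56e-05). Myeloid markers rose in 5 of 16 cases (camera adjusted p = 0.0401), with a mean log2(CPM + 1) of 4.461 and 4.38 in the libraries of sets B and A, 1.455 and 1.482 in those of set C, and 0.976 to 1.763 at day 0. Mature myofibre markers rose in 6 of 14 (0.0419), while glial markers fell in 7 of 10 (2.12e-05), fibro-adipogenic progenitor markers in 4 of 12 (0.00893) and mural cell markers in 2 of 10 (0.0107). In all, 4357 genes passed (2275 higher, 2082 lower, or 1987 and 2557 with DESeq2's size factors), against 2351 with near-identical pairs summed and 623 within processing set C.

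In the aged day 5 libraries (n = 2 against 4) Pax7 fell to 0.801 ± 0.269 CPM (log2 fold change −6.80 ± 1.35, adjusted p = 0.00256), Myod1 to 14 ± 0.558 CPM (adjusted p = 0.0416) and Myog to 0.585 ± 0.107 CPM (adjusted p = 0.0307). By list 9 of 25 quiescence and satellite cell genes fell and 1 rose (camera adjusted p = 0.000186), and of 22 myogenic differentiation genes 3 fell and 1 rose (camera adjusted p = 0.716), while with pairs summed 0 of either list passed. Endothelial markers rose in 12 of 12 cases, the receptor genes Flt1 and Tie1 32.4-fold each to 279 ± 2.22 and 444 ± 9.57 CPM (camera adjusted p = 5.79e-11). Myeloid markers rose in 11 of 16, with C1qc at 112 ± 7.59 CPM from no count, at least 4080-fold (camera adjusted p = 1.27e-10). Erythroid markers rose in 5 of 7 cases (2.24e-06), lymphocyte markers in 1 of 12 (0.000195) and mature myofibre markers in 1 of 14 (0.0189).

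Sex-linked genes set these 2 libraries apart from the other aged ones. Xist, the RNA of the inactive X chromosome, fell to 0.662 ± 0.143 CPM from 66.4 ± 22.5 CPM (adjusted p = 0.00142). The Y-linked genes Kdm5d and Uty rose to 8.93 ± 1.19 and 19.4 ± 0.0202 CPM (adjusted p = 0.00608 and 0.00744). By list 2 rose and 1 fell of 5 over all genes, and 4 rose and 1 fell over the list alone (camera adjusted p = 0.000147). In all, 2097 genes passed (1125 higher, 972 lower, or 1633 and 2281 by DESeq2). The count was 230 without aged day 5 replicate 1 and 2205 without aged day 0 replicate 4, and it was 4 when the near-identical pairs, which include these 2 libraries, were summed.

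At aged day 7 (n = 4 against 4) Myh8 rose to 67.6 ± 69.3 CPM from no count, at least 2640-fold (adjusted p = 0.000905), Myog 18-fold to 1070 ± 318 CPM (adjusted p = 0.029) and Mki67 16-fold to 79.8 ± 27.1 CPM (adjusted p = 0.0212). Gpha2, a glycoprotein hormone subunit, fell 375-fold (adjusted p = 0.00537). Cell cycle genes rose in 21 of 24 cases and fell in 1, with Top2a 28.1-fold higher (camera adjusted p = 1.51e-16). Extracellular matrix genes rose in 10 of 25, Lamb1 4.66-fold (camera adjusted p = 3.13e-07), and in 0 with near-identical pairs summed. The mean log2(CPM + 1) of that list was 9.651 and 9.687 in the set B pair against 6.377 and 6.428 at day 0 in sets B and A, and 8.147 and 8.263 against 7.615 and 8.015 in set C. Myogenic differentiation genes rose in 9 of 22 and fell in 1, with Mef2a 3.39-fold higher (camera adjusted p = 1.07e-05). Mature myofibre markers rose in 5 of 14 cases (0.00129) and glial markers fell in 5 of 10 (6.39e-05). In all, 2246 genes passed (1049 higher, 1197 lower, or 862 and 1808 with DESeq2's size factors). The count was 478 without aged day 0 replicate 2, 3307 without aged day 0 replicate 3, and 1 with near-identical pairs summed.

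At aged day 21 (n = 2 against 4) the neural and embryonic transcription factor gene Sox11 rose 17.8-fold to 5 ± 1.22 CPM (log2 fold change 4.15 ± 0.84, adjusted p = 0.0363). Pax7 (102 ± 0.549 CPM), Myod1 (187 ± 17 CPM), Myog (132 ± 11 CPM) and Mki67 (7.54 ± 0.0594 CPM) did not pass (adjusted p = 0.981, 0.978, 0.739 and 0.893). Oxidative phosphorylation genes fell in 12 of 23 cases over the list alone and in 0 over all genes, with Cox4i1 at 215 ± 64 CPM against 783 ± 686 CPM (camera adjusted p = 1.06e-06, and 0.00026 with the processing set as a term). The fall was not seen within set C, where the mean log2(CPM + 1) of the list was 6.968 and 6.499 at day 21 and 6.72 and 6.659 at day 0, against 8.643 and 8.65 in the day 0 libraries of sets B and A. Erythroid markers rose in 5 of 7 cases over the list alone and 0 over all genes (camera adjusted p = 9.54e-05), and myeloid markers were placed higher with no gene past the test (0.0118). In all, 13 genes passed (2 higher, 11 lower), against 3331 at an unadjusted p under 0.05 and 1471 by DESeq2. The count was 0 without aged day 21 replicate 1, 1 without replicate 2, 597 without aged day 0 replicate 3, and 0 with near-identical pairs summed.

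**Figure D3:**
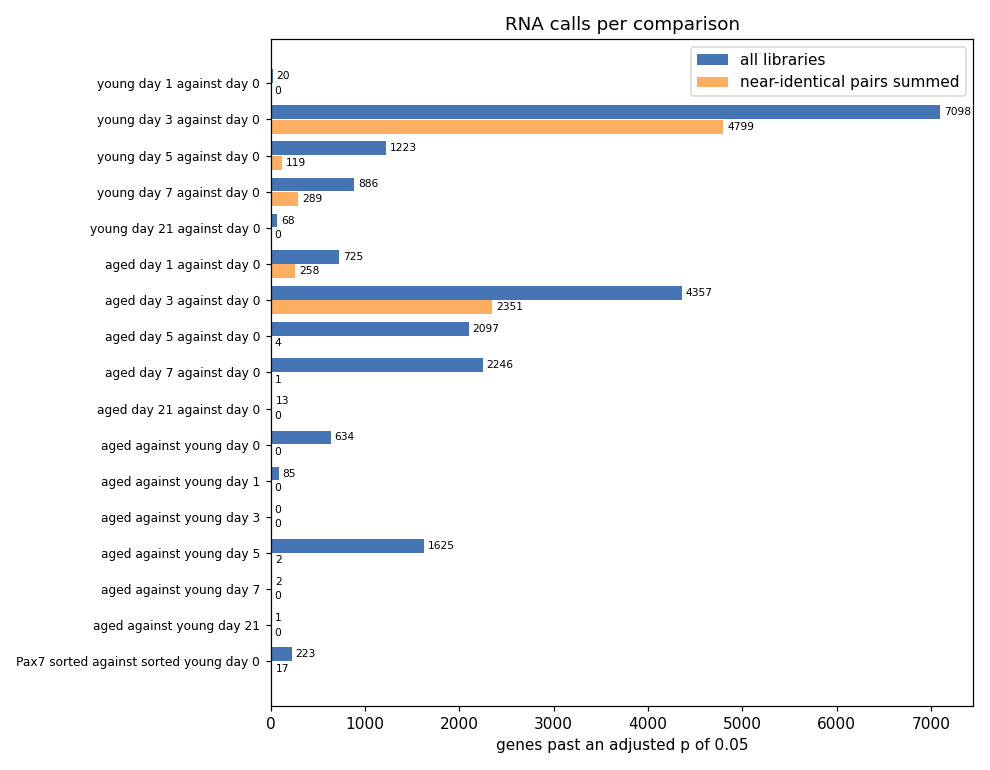
Number of genes past an adjusted p of 0.05 in each RNA comparison, as horizontal bars from 0, with all libraries and with near-identical pairs summed. The bars fall from 7098 to 4799 at young day 3 and from 4357 to 2351 at aged day 3, and from 2246 to 1 at aged day 7.

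Summing the near-identical pairs left 0 genes in 9 of the RNA comparisons by edgeR. At an unadjusted p under 0.05 these then had 1945 genes at young day 1, 3278 at young day 21, 1769 at aged day 21, and 3284, 1552, 424, 1333 and 2448 between ages at days 0, 1, 3, 7 and 21, and the interaction had 2044.

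Before injury, aged cells (n = 4) were set against young cells (n = 5). Lgi4, a secreted Schwann cell protein, was 21.6-fold higher at 119 ± 119 CPM (log2 fold change 4.43 ± 0.83, adjusted p = 0.00665). Sox11 was 24.6-fold lower at 0.279 ± 0.167 CPM (adjusted p = 0.00414). Pax7 did not pass (adjusted p = 0.517).

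By list, 7 of 24 cell cycle genes were lower in aged cells over all genes and 20 over the list alone, Top2a 10.4-fold (camera adjusted p = 1.07e-10). Young day 0 replicate 5 held 186 CPM of Top2a. Erythroid markers were lower in 5 of 7 cases (camera adjusted p = 1.13e-06). Endothelial markers were lower in 2 of 12, Flt1 10.7-fold (camera adjusted p = 0.00932), resting on young replicate 1, without which Flt1 no longer passed (adjusted p = 0.136). The mean log2(CPM + 1) of that list was 8.241 in that library, 2.486 to 4.877 in the other young ones and 2.902 to 5.109 in aged ones. Myeloid markers were lower in 1 of 16, C1qc at least 1120-fold (camera adjusted p = 0.0107), while glial markers were higher in 1 of 10 (1.97e-05) and mural cell markers were placed higher with 1 of 10 lower (0.0399). Of C1qc 167 CPM lay in young replicate 1. The Y-linked genes Kdm5d and Uty were lower (adjusted p = 0.0329 and 0.0354), resting on young replicate 1, without which Uty had an adjusted p = 0.648. Ddx3y, Eif2s3y and Xist did not pass (adjusted p = 0.172, 0.179 and 0.565; camera adjusted p = 0.0729). In all, 634 genes passed (124 higher, 510 lower). That was 105 without aged replicate 1, 1696 without young replicate 3 and 0 with pairs summed. Within set C 116 passed, mostly the other way (85 higher, 31 lower), where by group sizes each age is 1 batch.

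One day after injury, aged cells (n = 2) were set against young cells (n = 4). Cdca7, a target of E2F and Myc, was 10.7-fold higher at 45.1 ± 4.8 CPM (log2 fold change 3.42 ± 0.54, adjusted p = 0.00238), and Mcm4 4.47-fold. Apoe, the lipid carrier, was 9.06-fold lower at 553 ± 19.5 CPM (adjusted p = 0.0434). Cell cycle genes were higher in 4 of 24 cases over all genes and 14 over the list alone (camera adjusted p = 4.03e-24). With no marker past the test over all genes, erythroid (1.93e-05), mature myofibre (0.00107) and fibro-adipogenic progenitor markers (0.0414) were placed lower and myeloid markers higher (0.00438), the last against a median log2 fold change of −2.249. In all, 85 genes passed (72 higher, 13 lower), 52 with DESeq2's size factors and 498 by DESeq2 (197 higher, 301 lower). The count was 0 without aged day 1 replicate 2, 3 without replicate 1, 447 without young day 1 replicate 3 and 0 with near-identical pairs summed.

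At day 3 the aged (n = 4) and young cells (n = 5) were compared at the height of their response. Pax7 stood at 24.1 ± 11.6 and 18.2 ± 7.12 CPM, Myod1 at 639 ± 113 and 756 ± 151 CPM, Mki67 at 135 ± 52.7 and 119 ± 75 CPM, and Myog at 974 ± 268 and 2040 ± 1100 CPM (adjusted p = 1 for each). No gene passed in edgeR (0 genes, 612 at an unadjusted p under 0.05, 23 by DESeq2). The simulated data for this comparison showed 2% of 2-fold and 68% of 8-fold changes recovered. Camera placed interferon response genes higher in aged cells, with Irf7 at 40.6 ± 13.9 against 21.1 ± 10.7 CPM (camera adjusted p = 4.42e-14). Glial markers were higher in 4 of 10 cases over the list alone, Sox10 at 13 ± 3.27 against 3.64 ± 0.687 CPM (camera adjusted p = 5e-10). Myogenic differentiation was lower, with 1 gene over the list alone, Tnnt1 at 34.1 ± 7.95 against 139 ± 63.6 CPM (camera adjusted p = 5.51e-10). Endothelial markers were placed higher (9.76e-06) and mature myofibre markers lower (1.25e-05), with no gene past the test.

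At day 5 the comparison of ages (n = 2 against 3) carried the makeup of the aged day 5 libraries described above. Myog was at 0.585 ± 0.107 CPM in aged against 2910 ± 583 CPM in young cells (log2 fold change −12.26 ± 2.47, adjusted p = 0.00286) and Pax7 was 23.1-fold lower (adjusted p = 0.0192). Endothelial markers were higher in 12 of 12 cases, Tie1 47.2-fold (camera adjusted p = 3.31e-12), erythroid markers in 5 of 7 (0.000536), mural cell and fibro-adipogenic progenitor markers in 3 of 10 (0.000656) and 3 of 12 (0.00251) and glial markers in 2 of 10 (0.000178). Myogenic differentiation genes were lower in 13 of 22, Chrna1 180-fold (camera adjusted p = 1.15e-11). In all, 1625 genes passed (764 higher, 861 lower, or 939 and 663 with DESeq2's size factors). The count was 166 without aged day 5 replicate 1, 805 without young day 5 replicate 1 and 2 with near-identical pairs summed.

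At day 7 aged and young cells (n = 4 and 4) had Myog at 1070 ± 318 and 1000 ± 329 CPM and Mki67 at 79.8 ± 27.1 and 76.8 ± 30.8 CPM, which did not pass (adjusted p = 1 for both). Wdfy1, an endosomal adaptor, was 5.13-fold lower in aged cells at 12.9 ± 1.78 against 66.5 ± 20.3 CPM (log2 fold change −2.36 ± 0.38, adjusted p = 0.00941). Camera placed oxidative phosphorylation lower, with Ndufa9 at 95.4 ± 21.3 against 151 ± 41.9 CPM (camera adjusted p = 1.79e-06). The Notch pathway was placed higher, with the receptor gene Notch2 at 171 ± 76.4 against 40.7 ± 15.2 CPM (camera adjusted p = 0.00083). Quiescence was placed higher, with Col5a3 at 488 ± 6.51 against 106 ± 49.1 CPM (camera adjusted p = 0.00083). No member of these 3 lists passed in edgeR over all genes. In all, 2 genes passed (both lower), against 1652 at an unadjusted p under 0.05, 129 by DESeq2 (73 higher, 56 lower), 17 within processing set C (all higher), 1 with the replicate block, 0 without aged day 7 replicate 1 and 0 with near-identical pairs summed.

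At day 21 (n = 2 against 3) the ages had Pax7 at 102 ± 0.549 against 74.2 ± 48.3 CPM and Myog at 132 ± 11 against 62.3 ± 17.4 CPM (adjusted p = 0.882 and 0.766). Oxidative phosphorylation was placed lower in aged cells, with Uqcrfs1 at 75.9 ± 23 against 207 ± 113 CPM (camera adjusted p = 2.73e-07). Mean log2(CPM + 1) of the list was 6.968 and 6.499 in aged and 6.704, 8.213 and 8.155 in young replicates 1 to 3. A single gene passed (1, lower), against 2732 at an unadjusted p under 0.05 and 192 by DESeq2. The count was 1450 without young day 21 replicate 1. That library lay nearer aged day 21 replicate 2 than its group (18.1 against 230 times the sampling noise).

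The interaction of age and time called 803 genes (5182 at an unadjusted p under 0.05). It takes in both aged day 5 libraries, whose makeup it cannot tell from age. Across 22432 genes, which are not independent replicates, Pearson's r of the young and aged log2 fold changes was 0.47 at day 3 and 0.203 at day 7, and 0.056, −0.045 and 0.011 at days 1, 5 and 21. Spearman's rho was 0.584 and 0.304 at days 3 and 7, and 0.052, −0.016 and −0.04 at the other days. The interaction count was 257 without aged day 5 replicate 2, 258 without replicate 1, 2334 without young day 21 replicate 1, 1575 without young day 1 replicate 3 and 0 with near-identical pairs summed.

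Cells sorted as Pax7 positive (n = 3) were set against the other young day 0 cells (n = 5). Pax7 itself was at 24, 3.36 and 0.512 CPM in the 3 sorted libraries, 9.28 ± 12.8 CPM against 49.7 ± 38.7 CPM, and did not pass (adjusted p = 0.149). Fmnl1, a formin of blood cells, was 18.4-fold higher (log2 fold change 4.20 ± 0.64, adjusted p = 0.000588). Dbx1, a homeobox gene, had no count and was at least 183-fold lower (adjusted p = 0.000195). Lymphocyte markers were higher in 3 of 12 cases, among them Cd4 at 3.28 ± 2.86 CPM against no count, at least 231-fold (camera adjusted p = 4.59e-13). Extracellular matrix genes were higher in 6 of 25, Col6a2 7.46-fold (camera adjusted p = 1.18e-07). Endothelial markers were higher in 1 of 12, Kdr 7.89-fold (camera adjusted p = 5.11e-09). The sorted libraries differed, with a mean log2(CPM + 1) of 0.521 in replicate 1 against 2.75 and 2.364 for lymphocyte markers, and of 7.118 against 9.901 and 9.475 for extracellular matrix (5.894 to 8.716 in the other young libraries). Without replicate 2 Cd4, Col6a2 and Kdr no longer passed (adjusted p = 0.0516, 0.228 and 0.132), nor did the last 2 without replicate 3 (0.0749 and 0.26).

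Mature myofibre markers were higher in 2 of 14 cases, Myh1 18.4-fold and Actn3 5.39-fold, with 248 CPM of Myh1 in replicate 1 and 4.25 and 2.7 CPM in the others. Without replicate 1 both turned lower (log2 fold change −0.41 and −0.27; camera adjusted p = 1.51e-06). Myeloid markers had 0 of 16 genes past the test and Csf1r at 8.45, 441 and 836 CPM (camera adjusted p = 6.05e-07). Quiescence genes had 0 of 25 past it (camera adjusted p = 0.155), and of the sex-linked genes none passed, with Uty at an adjusted p = 0.0716 (camera adjusted p = 0.142). In all, 223 genes passed (124 higher, 99 lower, or 133 and 62 with DESeq2's size factors and 397 and 527 by DESeq2). The count was 44 without Pax7-sorted replicate 2, 660 without replicate 1, 1125 without young day 0 replicate 1 and 17 with near-identical pairs summed.

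Accessibility was tested on merged peaks, named by their place on mm10. In aged cells at day 3 (n = 4 against 7), 12229 peaks opened and 2767 closed of 237525 tested. A peak in Nkain3, a gene of a sodium pump interacting protein (chromosome 4, 20535846 to 20536134), opened to 3.94 ± 2.32 CPM from 0.236 ± 0.209 CPM (log2 fold change 4.59 ± 0.65, adjusted p = 6.82e-06). At Myog a peak (chromosome 1, 134289546 to 134290119) opened to 12.7 ± 7.03 CPM from 5.34 ± 1.35 CPM (log2 fold change 1.28 ± 0.40, adjusted p = 0.0375). The 29, 4 and 3 peaks tested at Pax7, Myod1 and Mki67 held no call. The total of 14996 was 4782 without aged day 3 replicate 4, 20429 without aged day 0 replicate 1, 7263 with no batch term and 2401 with the replicate block (2357 opened, 44 closed). With DESeq2's size factors 9517 opened and 3854 closed, and by DESeq2 12884 and 10037.

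Young day 3 against day 0 (n = 4 against 4) gave 664 opened and 52 closed peaks. The Myog peak stood at 15.9 ± 4.87 CPM against 4.8 ± 3.2 CPM and did not pass (log2 fold change 1.80 ± 0.61, adjusted p = 0.236). A peak in Ldlrad4, an inhibitor of TGF-β signalling (chromosome 18, 68119781 to 68120193), closed to 0.535 CPM from 5.93 CPM (log2 fold change −4.36 ± 0.85, adjusted p = 0.00309). Among the opened peaks were some with no read at day 0, such as in BC107364 (chromosome 3, 96451940 to 96452639, 10.3 ± 4.44 CPM, adjusted p = 3.57e-06). Of the 716 peaks called, 171 (23.9%) had no read in 1 of the groups. The count was 464 without young day 3 replicate 4, 2427 without young day 0 replicate 3 and 426 without the peaks that lacked reads.

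At day 7, aged cells (n = 4 against 7) had 92 opened and 4 closed peaks, with a peak in Camk2g, a calmodulin kinase gene (chromosome 14, 20780271 to 20780501), 8.6 against 0.703 CPM (log2 fold change 3.47, adjusted p = 0.00694). The count of 96 was 1 without aged day 0 replicate 5, 853 without aged day 7 replicate 4, 693 without libraries under 2 M reads and 2 with no batch term. With DESeq2's size factors 24 opened and 8 closed, and by DESeq2 more closed than opened (721 opened, 1087 closed). Young cells at day 7 (n = 5 against 4) had 3 closed peaks, of which 2 lie near Mid1 on chromosome X, such as 169997523 to 169998452 at 2.02 ± 1.28 against 27.2 ± 10.5 CPM (log2 fold change −4.00 ± 0.58, adjusted p = 0.00098). That count was 1 without young day 0 replicate 4, 4 without young day 0 replicate 1 and 0 with no batch term, where 10255 had an unadjusted p under 0.05 in the main model and DESeq2 called 19.

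Between ages, 875 peaks were more and 132 less open in aged cells at day 0 (n = 7 against 4), and 1158 and 47 at day 7 (n = 4 against 5). Among the more open ones were peaks without a read in the young libraries, on chromosome X (4899284 to 4899484, 23.4 ± 4.52 CPM, adjusted p = 4.43e-08) at day 0, and in Srp54b and Srp54c (chromosome 12, 55154885 to 55155391 and 55229692 to 55230452, 65.7 ± 17.5 and 74.2 ± 20.1 CPM) at day 7. These are near-identical copies of a signal recognition particle gene, so reads there could be shared. Reads in peaks of the Y chromosome at day 0 were at 240.5 to 555.4 per M reads in aged replicates 1 to 4, 48.1 to 67 in aged replicates 5 to 7 and 64.5 to 207.2 in young libraries, and sex was not tested apart from age. The peak in Ldlrad4 was less open in aged cells at day 7, 0.656 against 9.83 CPM (log2 fold change −3.85, adjusted p = 0.000791). Of the calls, 250 (24.8%) at day 0 and 486 (40.3%) at day 7 had no read in 1 group. The count of 1007 at day 0 was 285 without young day 0 replicate 3, 1319 without young day 0 replicate 4 and 664 without the peaks that lacked reads. The 1205 at day 7 were 772 without young day 7 replicate 1 and 579 without such peaks.

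At the other days few peaks differed between ages. At day 3 (n = 4 against 4) edgeR called 0 (8248 at an unadjusted p under 0.05, 37 by DESeq2), 39 with the replicate block, 1133 without aged day 3 replicate 1 and 189 without replicate 4. At day 5 (n = 2 against 2) 11 passed, among them peaks near Mid1 on chromosome X such as 169996863 to 169997406 at 66.3 ± 9.02 against 0.0851 CPM (log2 fold change 9.82, adjusted p = 9.1e-05). The count was 0 without young day 5 replicate 1 and 21 by DESeq2. At day 1 (n = 2 against 3) the 1 peak called lay near Mid1 as well (169997523 to 169998452, 71.5 ± 3.57 against 3.8 ± 3 CPM, adjusted p = 0.0439). Leaving out any 1 of the 5 libraries gave 0 peaks, and DESeq2 called 59 (13 more, 46 less open). Reads in peaks of the Y chromosome differed along with the Mid1 peaks, at 151.6 and 158 per M reads in aged against 25.7, 68.8 and 67.5 in young libraries at day 1, and 377.7 and 239.8 against 20.3 and 26.8 at day 5, where sex was not tested apart from age either. The deposited peak lists of aged day 0 stood at their cap of 300000 peaks in every library (n = 7), against a mean of 139669 in young day 0 (n = 4), so the difference is 160331 or more (exact permutation test, two-sided, p = 0.0061). Past a −log10 q of 2 they held 81467 ± 69849 and 47650 ± 21634 peaks (difference 33817, exact permutation p = 0.4). All 18 lists at the cap belong to the 22 libraries that have reads at peaks which the others lacked, so here too the ages cross these sets.

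Pax7-sorted against other young day 0 cells (n = 3 against 4) gave 2937 more and 511 less open peaks. A more open peak lay in Duxf3, a member of a repeated homeobox family (chromosome 10, 58232357 to 58232908), at 47.3 ± 22.6 CPM against no read, where reads could be shared between copies. A less open one lay in Mctp2 (chromosome 7, 72097026 to 72097253) at 0.0327 against 4.06 CPM (log2 fold change −7.25). The count of 3448 was 732 without young day 0 replicate 3, 13631 (6552 more, 7079 less open) without replicate 4, 440 with the replicate block, 839 with no batch term and 6897 with DESeq2's size factors.

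**Figure D4:**
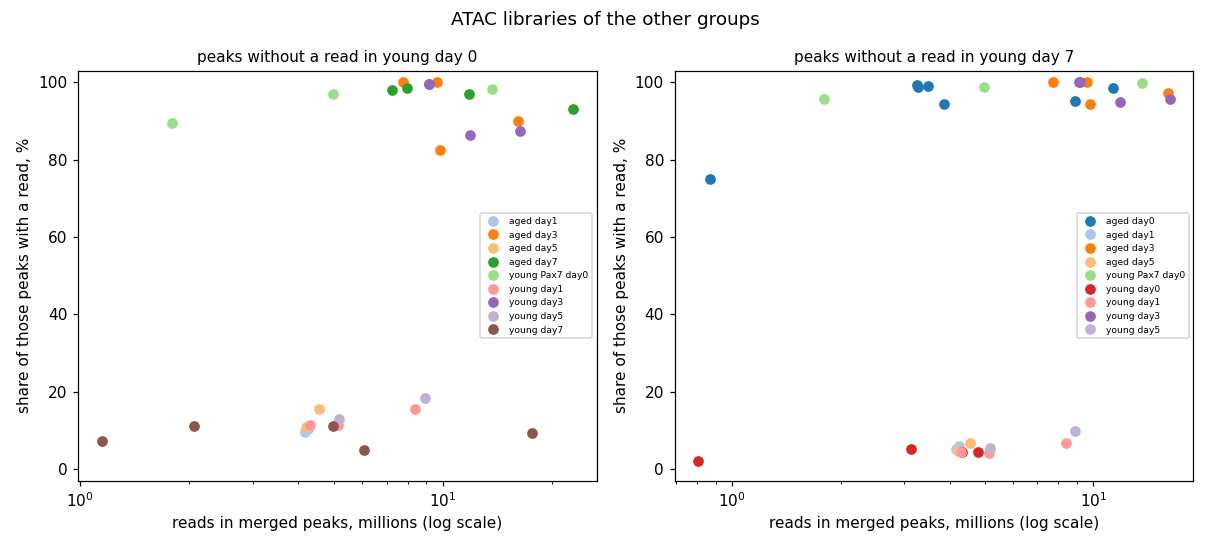
Share (%) of the peaks without a read in young day 0 (left) or young day 7 (right) that have a read in each library of the other groups, against its reads in merged peaks (M, log axis). The libraries split into 22 at 74.9% or more and 18 at 18.5% or less.

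Reads at such peaks followed sets of libraries rather than depth. There were 775 peaks with no read in any of 4 young day 0 libraries and a mean above 1 CPM in aged day 0, and 494 likewise at day 7. They had reads in 74.9% to 100% of cases in each of 22 libraries (aged day 0, day 3 and day 7, young day 3 and Pax7-sorted) and in 2.2% to 18.5% of cases in each of 18 libraries (young day 0 and day 7, and both ages at days 1 and 5). Young day 0 and day 7 libraries count here on the peaks of the other day alone, since by choice they have no read at those of their own day. The comparisons young day 3 against day 0, aged against young at days 0 and 7, and Pax7-sorted against young day 0 cross these sets, so there the set and the group cannot be told apart.

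Scaling moved some comparisons as a whole. With DESeq2's size factors the median log2 fold change of all genes shifted by −0.172 for aged day 1, −0.14 for aged day 3, −0.16 for aged day 7 and 0.166 for aged against young day 5. For peaks it shifted by 0.236 for young day 7, −0.144 and −0.265 for aged days 3 and 7, 0.271, 0.158 and −0.23 for the ages at days 0, 5 and 7, and 0.405 for Pax7-sorted cells.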

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

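The tests of the processing set, of other cell types for myogenic genes, of another animal source, of read handling, of age at ATAC peaks, of depth, of splits that part pairs and of splits of summed pairs were chosen only after the result was seen. Single libraries were compared with the rest of their group in 201 groups of 4 or more values, and 27 lay far from the others, where chance picks out about 1 in 20 groups (10.1 here). Of the 27, 14 were in young day 1 replicate 3.

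In young day 1 replicate 3 Myog was at 1370 CPM (next 95.4) and Mki67 at 71.5 CPM (next 4.42). Its mean log2(CPM + 1) was 6.43 for quiescence (next 7.229), 7.744 for myogenic differentiation (5.722), 6.203 for cell cycle (3.95), 7.187 for immediate early and stress response (9.397), 4.706 for Notch (5.041), 5.018 for TGF-β and BMP (6.028) and 8.483 for oxidative phosphorylation (7.412). For markers of other cells it was 7.008 for macrophages (1.401), 1.135 for lymphocytes (0.388), 6.076 for fibro-adipogenic progenitors (6.954), 5.487 for endothelium (4.28) and 4.513 for glia (7.985).

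This library differed from its nearest group member by 185.3 times the sampling noise and from young day 5 replicate 1 by 39.5 times. Against the processing set as the cause, the largest distance between set A and set B libraries of a group elsewhere was 53.2. Other cells as the source of the myogenic genes stay open, since Myog (14.4 times the next) itself flagged the library. C1qc (558 CPM) and Csf1r (281 CPM) point to myeloid RNA, which a flow sort for stem cells should remove. A later-day library under a day 1 label may explain it, but of 1415 genes separating young day 5 from day 1 only 80.2% lay nearer day 5, between the bounds set (over 90% and under 50%), so it cannot be told apart from a day 1 animal further along in its response. No biological explanation was tested.

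In both aged day 5 RNA libraries 4 genes of muscle stem cells were low. Pax7, Myf5, Myod1 and Myog were at 4.29%, 2.32%, 5.64% and 0.0201% of young day 5, so cells other than muscle stem cells, which a flow sort for stem cells should remove, are a candidate explanation, although the satellite cell list still averaged 5.388 and 5.418 log2(CPM + 1) against 6.331 to 7.683 at aged day 0. Material from another animal source is another, since Ddx3y was at 164.9 CPM or more in both and 0 in the other aged libraries. Loss of the stem cell state with age at day 5 stays open. Aged day 5 accessibility of the Myf5, Pax7 and Myod1 spans was 67.2%, 112.9% and 120.9% of young day 5, but in other libraries, which may be other samples. Uninjured young day 0 replicate 1 had like myeloid (7.251) and endothelial levels (8.241), but is 1 library. The 2 aged day 5 RNA libraries are a near-identical pair and may be 1 sample.

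Some ATAC peaks had reads in 22 libraries and almost none in 18. Against age, the lowest share of the day 0 peaks with a read in a young day 3 or Pax7-sorted library was 86.5%. Against depth, the deepest library of the 18 (17.606 M reads) had reads in 9.3% of the day 0 peaks, and the shallowest of the 22 (0.869 M) in 74.9% of the day 7 peaks. Different read handling before deposition may explain it. Aged against young day 7 and young day 3 against day 0 shared 473 peaks called higher (3.24 if independent). Both cross the sets, so any cause of them could give this. Differences of age at the remaining peaks were not tested apart from these sets.

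Elsewhere, Myod1 was at 313 CPM in aged day 7 replicate 3 (next 246), Myog at 111 CPM in aged day 0 replicate 4 (next 43) and at 533 CPM in young day 0 replicate 3 (next 92.7). Mki67 was at 56.7 CPM in aged day 3 replicate 1 (next 153) and 120 CPM in aged day 7 replicate 3 (next 71.3). Mean log2(CPM + 1) stood apart for macrophage markers in young day 0 replicate 1 (7.251, next 2.146), lymphocyte markers in young day 7 replicate 2 (0.486, next 0.233), fibro-adipogenic progenitor markers in aged day 0 replicate 3 (5.472, next 6.184) and endothelial markers in aged day 3 replicate 3 (3.541, next 2.931). It did so too for mural cell markers in young day 1 replicate 2 (6.43, next 5.771) and young day 3 replicate 4 (5.286, next 4.815), and for glial markers in aged day 0 replicate 4 (6.998, next 6.596) and young day 0 replicate 5 (3.258, next 5.32). The interaction test called 803 genes, with the aged day 5 libraries included.

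Other splits of the same libraries were tested for each comparison of 3 or more against 3 or more. Under 5% of splits gave as many genes for young day 3 (1 of 100, 7098 against at most 3224 in another). So it was for aged day 3 (1 of 35, 4357 against 4051). With near-identical pairs summed both held (1 of 100, 4799 against 4563, and 1 of 35, 2351 against 717). The shares are unadjusted over comparisons. For aged day 7 (1 of 35, 2246 against 1853) both groups hold such a pair, and summed they leave 10 splits (1 gene against 0), too few for a share under 5%. Chance cannot be excluded for young day 1 (66 of 100, 20 against 3184), young day 5 (4 of 56, 1223 against 1775), young day 7 (13 of 100, 886 against 4337) and young day 21 (33 of 56, 68 against 4083). Nor can it be for the ages at day 0 (31 of 100, 634 against 6630) and day 7 (2 of 35, 2 against 266), or for Pax7-sorted cells (25 of 56, 223 against 3743). For the ages at day 3 no gene was called, a count that all 100 splits reach, so the splits decide nothing (highest other 370). Splits with several times the real count point to a structure of the samples. At young day 1 the highest other split joined the set A libraries of both days, and the count was 201 with the processing set as a term. At young day 7, aged days 3 and 7 and the ages at days 0, 3 and 7 it parted set C from the rest. Within set C these gave 381, 623, 2, 116, 0 (edgeR, 267 at an unadjusted p under 0.05) and 17, in that order. Where every pair passed the limit, 8 of 35 splits part as many pairs as the real one. Of those the highest other gave 0 genes against 4357 for aged day 3 (4935 with the replicate block), 223 against 2246 for aged day 7 (2754) and 1 against 2 for the ages at day 7, and the splits with higher counts keep pairs together.

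For peaks, on 10000 of them, chance can be excluded for young day 3 (1 of 35, 29 against 0), aged day 3 (2 of 100, 597 against 776) and the ages at day 0 (3 of 100, 35 against 98) and day 7 (3 of 100, 51 against 594). It cannot be excluded for aged day 7 (19 of 100, 7 against 264) and Pax7-sorted cells (3 of 35, 154 against 685). For young day 7 (0 against 417 in 100 splits) and the ages at day 3 (0 against 109 in 35) all splits reach the 0 peaks called, which decides nothing. In the ages at day 3, among the 8 splits that part as many pairs, the highest other gave 2 peaks against 0 (39 with the replicate block). For all but young day 3, higher counts of other splits also point to a structure of the samples. For the ages at days 0 and 7 and Pax7-sorted cells that split kept whole batches together, and for the ages at day 3 each side had 3 of its 4 libraries from 1 batch, while the batch is a term in all these counts.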

How the results depend on the processing

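The tests with the processing set, within processing set C, with near-identical pairs summed, with mitochondrial genes or the sum library kept, and without the Y-linked libraries, the ATAC libraries under 2 M reads or the peaks that lacked reads were chosen only after the data were seen. Of 335 gene results that the naming rule gave 196 passed, and 109 of these passed without each replicate in turn. All 29 named peaks passed and 19 did so without each replicate. For results that moved below the cause was not tested, except where the setting itself leaves fewer libraries or tests more or fewer genes or peaks.

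Named genes that had passed no longer did in 111 cases with near-identical pairs summed (85 did), 74 within set C (60 did), 40 without the filter on low counts (156), 33 with the replicate block (163), 16 without libraries holding Y-linked reads (150), 12 with the processing set as a term (184), 2 with DESeq2's size factors (194) and 1 with DESeq2 (183). With mitochondrial genes kept and with the sum library kept, all 196 passed in the same direction. Among named genes that had not passed, 35 did with DESeq2, 19 with the processing set as a term, 14 with the sum library kept, 9 without Y-linked libraries, 6 within set C and 4 with the block. Of the 29 peaks 8 no longer passed with no batch term, 7 with the replicate block, 2 without libraries under 2 M reads, 1 with DESeq2's size factors and 1 with library totals, and all passed with DESeq2 and without the filter.

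The numbers past the threshold moved by over 1.5 times as follows. DESeq2 gave 478 for young day 1, 2587 for young day 5, 1948 for young day 7, 1059 for young day 21, 1928 for aged day 1, 3914 for aged day 5, 4170 for aged day 7, 1471 for aged day 21, 1787 for the ages at day 0, 498 for the ages at day 1, 23 for the ages at day 3, 3125 for the ages at day 5, 129 for the ages at day 7, 192 for the ages at day 21, 924 for Pax7-sorted cells and 3049 for the interaction. For peaks the same choice gave 3203 for young day 3, 19 for young day 7, 22921 for aged day 3, 1808 for aged day 7, 2395 for the ages at day 0, 59 for the ages at day 1, 37 for the ages at day 3, 21 for the ages at day 5 and 21287 for Pax7-sorted cells. Without the filter on low counts, so with more genes tested, edgeR gave 719 for young day 5, 473 for young day 7, 4 for young day 21, 365 for aged day 1, 1141 for aged day 5, 0 for aged day 21, 195 for the ages at day 0, 14 for the ages at day 1, 956 for the ages at day 5, 0 for the ages at day 21, 108 for Pax7-sorted cells and 412 for the interaction (edgeR, unadjusted p under 0.05: 3554 for aged day 21 and 2624 for the ages at day 21). With DESeq2's size factors it gave 22 for aged day 21 and 52 for the ages at day 1. For peaks the same choice gave 32 for aged day 7 and 6897 for Pax7-sorted cells. With library totals the peaks were 55 for aged day 7 and 5905 for Pax7-sorted cells.

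With the replicate block the genes were 40 for aged day 21, 265 for the ages at day 0, 164 for the ages at day 1, 1 for the ages at day 7 and 441 for Pax7-sorted cells. For peaks the same choice gave 463 for young day 3, 2401 for aged day 3, 1 for aged day 7, 0 for the ages at day 1, 39 for the ages at day 3 and 440 for Pax7-sorted cells (edgeR, unadjusted p under 0.05: 8544 for the ages at day 1). Log2 fold changes of genes that had not passed turned with the block for Pax7 (0.28) and Myod1 (1.02) at young day 1, Myod1 (0.02) at young day 5, Myod1 (0.16) at young day 7, Mki67 (0.55) at aged day 5. In the 4 comparisons the methods name numbers largely follow set or batch, so the block was a check.

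Summing near-identical pairs, so with fewer libraries, gave 0 for young day 1, 119 for young day 5, 289 for young day 7, 0 for young day 21, 258 for aged day 1, 2351 for aged day 3, 4 for aged day 5, 1 for aged day 7, 0 for aged day 21, 0 for the ages at day 0, 0 for the ages at day 1, 2 for the ages at day 5, 0 for the ages at day 7, 0 for the ages at day 21, 17 for Pax7-sorted cells and 0 for the interaction. The report gives the numbers at an unadjusted p under 0.05 for these counts of 0. Fold changes turned for Pax7 (−0.01) at aged day 21, Mki67 (−0.05) between the ages at day 3. Pearson's r of the young and aged fold changes was then 0.42 at day 3 and 0.173 at day 7. With the processing set as a term edgeR gave 201 for young day 1, 2047 for young day 5, 2409 for young day 21, 1750 for aged day 1, 3537 for aged day 7, 38 for aged day 21, 1389 for the ages at day 0, 233 for the ages at day 1, 0 for the ages at day 21, 1252 for Pax7-sorted cells and 2829 for the interaction (edgeR, unadjusted p under 0.05: 4043 for the ages at day 21). Fold changes turned for Pax7 (0.79) and Xist (0.00) at young day 1, Myog (0.20) at young day 21, Mki67 (1.32) at aged day 5, Pax7 (−0.25) at aged day 21, and r was 0.129, 0.52, 0.027 and 0.263 at days 1, 3, 5 and 7.

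Within set C, with fewer libraries, counts were 1831, 381 and 951 for young days 3, 7 and 21. For aged days 3, 7 and 21 they were 623, 2 and 1. The ages at days 0, 7 and 21 gave 116, 17 and 0 (edgeR, unadjusted p under 0.05 at day 21: 2797). Pax7-sorted cells gave 917. By group sizes, batch there goes with young day 3, day 21 and age at days 0 and 7. Fold changes there turned for Myod1 (−0.50) at young day 3, Spp1 (0.11) at young day 7, Myog (1.04) at young day 21, Pax7 (−0.26), Myod1 (0.05), Mki67 (−0.27), Cox7a2 (0.05) and Cox4i1 (0.24) at aged day 21, Myog (1.32), B2m (−0.63) and Emcn (1.02) between the ages at day 0, Mki67 (−0.25) between the ages at day 3, Myod1 (0.17), Myog (−0.05) and Mki67 (−0.03) between the ages at day 7, of which Spp1 alone had passed with all libraries. With the sum library kept, which counts 3 libraries again, edgeR gave 137 for young day 1, 137 for young day 21, 26 for aged day 21 and 479 for Pax7-sorted cells. The fold change turned for Myod1 (0.04) at young day 1. Without libraries that hold Y-linked reads it gave 56 for young day 1, 222 for young day 21, 8 for aged day 21, 1 for the ages at day 3, 0 for the ages at day 21 and 972 for Pax7-sorted cells (edgeR, unadjusted p under 0.05: 2939 for the ages at day 21). Fold changes turned for Myog (−0.02) and Mki67 (−0.05) between the ages at day 7.

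For ATAC, with no batch term edgeR gave 0 for young day 7, 7263 for aged day 3, 2 for aged day 7, 0 for the ages at day 1, 2 for the ages at day 5 and 839 for Pax7-sorted cells (edgeR, unadjusted p under 0.05: 10134 for young day 7 and 4778 for the ages at day 1). Without libraries under 2 M reads it gave 477 for young day 3, 0 for young day 7 and 693 for aged day 7 (edgeR, unadjusted p under 0.05: 13312 for young day 7). Without the peaks that lacked reads in a set, on 236562 peaks, it gave 426 for young day 3, 664 for the ages at day 0 and 579 for the ages at day 7. The difference of peaks per library between aged and young day 0 was 33817 past a −log10 q of 2, where it no longer passed, against 160331 or more. The camera test with an estimated correlation called 0 of the 391 gene list tests (45 at an unadjusted p under 0.05).

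Leaving out 1 replicate (r) at a time gave ranges, with the library left out in brackets. For genes they were 2 (young day 0 r5) to 296 (young day 0 r3) for young day 1, 280 (young day 5 r2) to 1814 (young day 0 r3) for young day 5, 250 (young day 7 r3) to 1280 (young day 0 r3) for young day 7 and 0 (young day 21 r2) to 1306 (young day 21 r1) for young day 21. They were also 243 (aged day 1 r1) to 838 (aged day 0 r3) for aged day 1, 230 (aged day 5 r1) to 2205 (aged day 0 r4) for aged day 5, 478 (aged day 0 r2) to 3307 (aged day 0 r3) for aged day 7 and 0 (aged day 21 r1) to 597 (aged day 0 r3) for aged day 21. Others were 105 (aged day 0 r1) to 1696 (young day 0 r3) for the ages at day 0, 0 (aged day 1 r2) to 447 (young day 1 r3) for the ages at day 1, 166 (aged day 5 r1) to 805 (young day 5 r1) for the ages at day 5 and 0 (aged day 7 r1) to 2 (young day 7 r1) for the ages at day 7. Further ranges were 0 (aged day 21 r1) to 1450 (young day 21 r1) for the ages at day 21, 44 (young Pax7 day 0 r2) to 1125 (young day 0 r1) for Pax7-sorted cells and 257 (aged day 5 r2) to 2334 (young day 21 r1) for the interaction. For peaks the ranges were 464 (young day 3 r4) to 2427 (young day 0 r3) for young day 3, 1 (young day 0 r4) to 4 (young day 0 r1) for young day 7, 4782 (aged day 3 r4) to 20429 (aged day 0 r1) for aged day 3 and 1 (aged day 0 r5) to 853 (aged day 7 r4) for aged day 7. Also for peaks they were 285 (young day 0 r3) to 1319 (young day 0 r4) for the ages at day 0, 0 (without any 1 library) for the ages at day 1, 0 (aged day 3 r2) to 1133 (aged day 3 r1) for the ages at day 3 and 0 (young day 5 r1) to 9 (aged day 5 r2) for the ages at day 5. The last peak ranges were 772 (young day 7 r1) to 1197 (aged day 7 r4) for the ages at day 7 and 732 (young day 0 r3) to 13631 (young day 0 r4) for Pax7-sorted cells. For the lowest counts of 0 by edgeR, the numbers at an unadjusted p under 0.05 were 2237 for young day 21, 1912 for aged day 21, 1138 for the ages at day 1, 1409 for the ages at day 7 and 1772 for the ages at day 21 in genes and 8221 for the ages at day 1, 1898 for the ages at day 3 and 4908 for the ages at day 5 in peaks.

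Log2 fold changes of named genes that turned without 1 replicate had these ranges, for genes that had not passed unless stated. They were Pax7 −0.48 to 0.26, Myod1 −0.43 to 1.07, Myog −0.72 to 3.41, Mki67 −3.14 to 0.00, Uty −8.80 to 1.41 and Xist −0.85 to 0.18 at young day 1, Myod1 −1.37 to 0.13 at young day 5 and Myod1 −1.28 to 0.33 at young day 7. Further ranges were Pax7 −0.10 to 0.95 and Myog −1.53 to 0.66 at young day 21, Myog −0.55 to 0.08 at aged day 1 and Mki67 −0.85 to 0.34 at aged day 5. Others were Pax7 −0.03 to 0.51 at aged day 21, Myog −1.73 to 0.56 and Uty −10.33 (aged day 0 replicate 2) to 1.28 (young day 0 replicate 1) between the ages at day 0 and Myod1 −0.05 to 0.44 between the ages at day 1. There were also Mki67 −0.03 to 0.45 between the ages at day 3, Myod1 −0.36 to 0.19, Myog −0.14 to 0.25 and Mki67 −0.21 to 0.22 between the ages at day 7 and Mki67 −0.20 to 2.10 between the ages at day 21. The last were Myod1 −4.94 to 0.21, Myog −4.64 to 2.46, Myh1 −0.41 (young Pax7 day 0 replicate 1) to 4.82 (young day 0 replicate 3), Actn3 −0.27 (young Pax7 day 0 replicate 1) to 2.94 (young Pax7 day 0 replicate 2), Acta1 −0.39 to 4.01, Uty −10.33 to 0.95, Kdm5d −6.30 to 0.84 and Xist −1.31 to 1.07 in Pax7-sorted cells. Of these, Myh1, Actn3 and (between the ages at day 0) Uty had passed with all libraries.

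Not run were the planned analysis of promoters and of windows of 2 kb around transcription starts, since no starts of mm10 were at hand, an RNA batch term, since the deposited RNA batch table names no library, and ATAC tests at day 21, for which peak lists but no counts were at hand. Smaller changes would mostly be missed, since edgeR recovered at most 6% of simulated 2-fold changes.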

Other observations

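All tests of this part were chosen only after the results were seen. At aged day 3, 1019 genes had both an RNA call and a called peak in or within 1 kb of their span, and 72% moved the same way in both, against 55.3% if the assays were independent. At young day 3 it was 57.3% of 89 genes against 48.8%. Genes are not independent replicates, so no p-value is given. Young day 0 replicate 1 in RNA lay nearest aged day 5 replicate 1 (77.2 against 155 times the noise to its own group).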
